A study of Drosophila melanogaster with 2 samples.

How the data were processed

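Gene expression in whole female Drosophila melanogaster larvae was measured on 2 two-colour oligonucleotide arrays, each with ablated RNA in 1 channel and control RNA in the other. Per the labels, ablated RNA carried Cy5 on replicate 1 and Cy3 on replicate 2. The treatment text in the labels gives the temperatures at which GAL80 blocks and permits the driver the opposite way from the series design text; the design text, with cell death induced at 30 °C, was followed.

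Per the file headers, the arrays were scanned and quantified with GenePix Pro 7.1.25, and the deposited values are spot intensity medians and local background medians at 635 nm (Cy5) and 532 nm (Cy3), with the percent of saturated pixels per spot, also deposited. The authors deposited in addition a table of log2 ratios. Set against the scanner values, its column for replicate 1 runs as 635 over 532 nm (r = 1) and that for replicate 2 the other way (r = -0.998), so both run as ablated over control; they were not centred, with medians of 0.487 and -0.115. What further normalization the authors applied is not given in the sources used here.

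Each array held 15552 spots in 48 blocks, of which 14785 were gene spots for 14593 distinct probes, 418 were empty and 188 carried DMNC identifiers. Probe transcript names were matched to gene symbols through the reference gene table, 12687 probes by locus tag and 1218 by synonym; 688 kept the name in the file. They represented 13137 genes. The median signal over background of gene spots was 96 (635 nm) and 93 (532 nm) on replicate 1 and 1 and 10 on replicate 2. Over 12 probes printed 17 times, the median SD of the log2 ratio between copies was 0.18 on replicate 1 and 0.19 on replicate 2.

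Background was corrected with normexp (offset 50) and ratios were normalized by loess within each array in limma 3.58.1 (R 4.3.3), with control spots at weight 0. Spots of a probe were averaged, the probe of highest intensity stood for a gene (further probes of p53, mld and upd3, which had the opposite sign, were not above background in any channel), and replicate 2 was turned so that every ratio runs as ablated over control. A spot was above background when its median exceeded the local background median by 2 SD; probes below this in all channels of both arrays were left out, leaving 5971 genes. Where the RNA of a group was not above background on either array, a bound of the fold was computed from channel values after loess and Aquantile, taking for the dim group the higher of its own signal and the lowest signal above background on that array. That floor is the lowest over all probes and not the detection limit of the spot. The bound is therefore lenient and can equal the measured fold. Genes were tested two-sided with lmFit and eBayes on the 2 log2 ratios against 0, with Benjamini-Hochberg adjustment. Lists were tested with camera at a preset correlation of 0.01, beside an estimated correlation and fry, for lists with at least 5 tested members.

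The comparison, the lists and the rule for named genes were set before the data were examined. The rule takes egr, rn, Tb and Ilp8; the 12 highest and 12 lowest means among called genes, filled where fewer passed with the largest means among genes at least 2-fold that way on both arrays; and in each list the 4 tested members with the smallest p. Alternatives were plain background subtraction, no background correction, a normexp offset of 16, print-tip loess, median centring, Aquantile between arrays, no filter and a stricter filter on dim probes, the authors' log2 ratios, the mean over probes, a trend in eBayes, each array left out, an adjusted p of 0.1 and a 1.5-fold threshold. After seeing the data, the mean of spot pixels, replicate 2 with its sign turned and a separate-channel model without a dye term were added. The separate-channel model with a dye term could not be fitted.

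Tested on simulated data with the spread observed in these arrays (5971 genes, 200 changed), the gene test recovered 0% of genes changed by a log2 ratio of 1 or 2 and 45% of those changed by 4; with the spread scaled by 0.1 it recovered 79.5%, 90% and 98%. For a list of 9 genes shifted by -1 on the log2 scale, camera with the preset correlation gave p under 0.05 in 50 of 50 simulations and with an estimated correlation in 0 of 50 (fry in 50 of 50). For an unshifted list the numbers were 0, 0 and 0 of 50. The simulations drew every gene and array independently. In these data the salivary glue list had an estimated correlation of 0.56, and the arrays ran against each other across genes (r = -0.53). The simulated numbers therefore do not show how the list tests behave here.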

Results

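RNA from whole female larvae was compared on 2 two-colour arrays. The ablated larvae expressed eiger, a tumour necrosis factor ligand that triggers cell death, in the pouch of the wing imaginal disc (the larval precursor of the wing) through a rotund driver held in check by temperature-sensitive GAL80. Controls carried the TM6 balancer chromosome with the Tubby marker and a GAL80 transgene. Both were kept for 24 h at 30 °C, and each array set 1 ablated RNA against 1 control RNA, with the dyes exchanged between replicates 1 and 2. The titles of both arrays give day 6. Nothing in the labels says whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Of 14785 gene spots, 38.1% (ablated) and 26.9% (control) were above local background on replicate 1, against 17.6% (ablated) and 15.0% (control) on replicate 2. The number of arrays limits the precision of every value below. Errors are SD over the 2 arrays (n = 2) of the log2 ratio of ablated to control larvae.

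The question was which transcripts of the whole larva differ when the wing disc has been damaged. Of the 24 lists tested with camera at a preset correlation, the salivary glue genes had the smallest p. They encode the secretion that fixes the pupa to its substrate. This list fell as a group in ablated larvae: its 9 tested members had a median log2 ratio of -1.44, 7 of them were lower on both arrays and 0 were higher on both. Among them were Sgs5 at -1.78 ± 0.29, Sgs8 at -1.84 ± 0.49, Sgs3 at -1.56 ± 0.39 and Sgs7 at -2.03 ± 1.18. The list passed camera with a preset correlation (adjusted p = 2.43e-07 over 24 lists), but not with an estimated correlation (adjusted p = 0.715) or with fry (adjusted p = 0.470). Adjusted over the list alone 3 members passed, Sgs5, Sgs8 and Sgs3, and over all genes tested 0 passed. In ablated larvae each of these 4 genes was above background on 1 of the 2 arrays, and Sgs3 was above background on replicate 1 only. The list median was -0.80 on replicate 1 and -1.84 on replicate 2, and it ranged from -2.13 to -0.79 over processing alternatives with the labelled sign. With the stricter filter on dim probes, 0 members were left to test. In the authors' values, which are not centred, 3 of 7 tested members lay below 0 and 1 above 0 on both arrays. The list medians there were 0.0140 on replicate 1 and -2.39 on replicate 2. The medians of all their values were 0.487 and -0.115, so the list median lay below that of the array on both replicates. With the sign of replicate 2 turned, the list median was 0.34 and the list no longer passed.

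**Figure D1:**
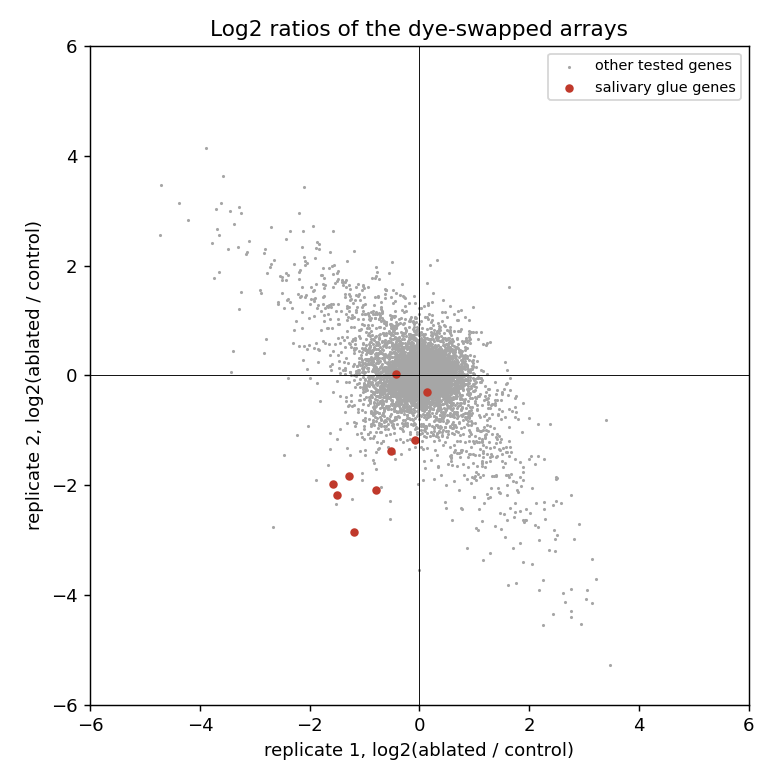
Log2 ratio of ablated to control larvae on replicate 1 (x axis) and replicate 2 (y axis), 1 point per tested gene (5971 genes), with the salivary glue genes in red. Of the 9 glue genes, 7 lie below 0 on both arrays, while most genes with large ratios lie along the diagonal of opposite signs (r = -0.53 across genes).

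At the level of single genes, 24 differed at least 2-fold in the same direction on both arrays, 1 higher and 23 lower in ablated larvae, and 346 differed at least 2-fold in opposite directions. The 1 higher gene was Cyp6a23, a cytochrome P450, at 1.63 ± 0.00975; it was above background on replicate 2 only and ran the other way in the authors' values (-0.82). With the sign of replicate 2 turned, 0 of these 24 genes were at least 2-fold on both arrays; Gpdh1 averaged 0.0529 and Cyp6a23 0.00689. As labelled, the lowest values were those of Gpdh1, glycerol-3-phosphate dehydrogenase, at -2.71 ± 0.0748, and of Sgs7. Other probes of Gpdh1 gave -0.72 and 0.14, so the probes of this gene disagree. Over processing alternatives with the labelled sign Gpdh1 ranged from -6.17 to -0.97, Sgs3 from -5.47 to -1.38 and LysB from -4.02 to -1.71, so the SD between arrays understates how uncertain these values are. In all, 16 named genes moved by more than 1 on the log2 scale under some alternative, Hsp23, Mf and Lcp65Ag1 below among them. The lysozyme genes LysB and LysD, near-identical copies whose separate values are uncertain, stood at -1.90 ± 0.00897 and -1.49 ± 0.20. The wing vein gene px stood at -1.93 ± 0.59 and CG32750 at -1.65 ± 0.0253. For 3 further genes the ablated larvae were not well above background on either array, so their folds are uncertain. CG15042 measured 3.89-fold higher in the control larvae, which is no minimum, since its bound equals the measured fold. The same holds for IKKbeta, a kinase of the immune deficiency pathway, at 3.33-fold higher in the control larvae. The third, stumps, an adaptor of fibroblast growth factor receptors, was at least 2.83-fold higher in the control larvae. Their log2 ratios on replicates 1 and 2 were -2.47 and -1.44 for CG15042, -1.22 and -2.25 for IKKbeta and -2.24 and -1.09 for stumps, whose mean ranged from -6.62 to -1.43 over processing alternatives. The control larvae were above background on 1 array for each. Such bounds hold for the mean over both arrays under the reported processing, and not for each array. Of the 16 given for named genes, 8 equal the measured fold within 0.01 on the log2 scale. They are those of AkhR, CG15042, Hsp70Ba, IKKbeta, Mcm7, Nopp140, SREBP and dpp, for which the value is the measured fold and no minimum. In 14 of the 16 the brighter group was above background on 1 array only. Over processing alternatives the mean of several of these genes fell below its bound. The mean log2 ratio nearest 0 was -1.73 for CG15042 (-1.96 as reported) and -1.49 for IKKbeta (-1.74 as reported). These single-gene values are given without a call, since 0 of the 5971 genes passed limma at a Benjamini-Hochberg adjusted p of 0.05; the lowest adjusted p was 0.996. At an unadjusted p under 0.05 there were 144 genes, fewer than this threshold passes by chance alone among 5971 genes, with 32 higher and 112 lower. This split also moved, to 59 and 43 with median centring, 62 and 28 in the authors' values and 420 and 423 with the sign of replicate 2 turned. The separate-channel model without a dye term also called 0 genes, with 183 at an unadjusted p under 0.05.

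The split of 1 higher and 23 lower genes depended on the background correction, at 6 and 20 without it and 36 and 95 with plain subtraction, and on median centring, at 7 and 12. It was 1 and 22 with print-tip loess and 1 and 23 with Aquantile after loess. In the authors' values, which differ in several choices at once, it was 160 and 31. Median centring and the authors' values also moved the median log2 ratio of all genes, to 0.14 and 0.31.

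Across genes, the log2 ratios of the dye-swapped arrays ran against each other, with Pearson's r = -0.53 and Spearman's rho = -0.23 over 5971 genes, which are not independent replicates. The value lies below -0.3, so the direction of single genes is unsettled. The labelled dyes were kept, since the labels state them and the authors' values turn the arrays the same way. Those values may rest on the same dye record, so they are no separate evidence for the direction. Read with the sign of replicate 2 turned, limma called 515 genes at adjusted p 0.05, 261 higher and 254 lower, and 346 genes were at least 2-fold on both arrays, 171 higher and 175 lower. No list passed camera in that reading.

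Among the genes that the design itself touches, egr and Tb gave no check of the labels, and rn and Ilp8 differed in sign between arrays. Neither the egr probe nor the Tb probe was above background in any channel, so neither gives a difference between the groups. For rn, the driver locus, the brighter probe read 0.34 on replicate 1 and -0.95 on replicate 2 (-0.30 ± 0.91), and a further probe averaged 0.0405. Ilp8, an insulin-like peptide released by damaged discs, read 1.05 on replicate 1 and -0.99 on replicate 2 (0.0315 ± 1.44) as labelled, but neither channel of its probe was above background on replicate 2. For rn the ablated larvae were above background on replicate 1 only and the controls on replicate 2 only. With the sign of replicate 2 turned, Ilp8 averaged 1.02 and rn 0.64. The planned test of chromosome 3 among called genes had 0 genes to run on.

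Beyond the glue genes, 2 lists passed camera with the preset correlation. Cuticle genes, structural proteins of the larval exoskeleton, were lower as a list (median -0.15, adjusted p = 0.0247; adjusted p = 0.715 with an estimated correlation). Of 25 tested members, 1 was higher and 12 were lower on both arrays, with Lcp1 at -0.999 ± 0.31, Ccp84Aa at -0.75 ± 0.0784, Lcp65Ag1 at least 1.31-fold higher in the control larvae and TwdlJ at -0.47 ± 0.0964. The list median was -0.23 on replicate 1 and -0.14 on replicate 2. Only the controls carry the Tubby marker, and Tb is itself on this list, though not among its tested members. A difference in cuticle genes from this marker cannot be told apart from a response to ablation. Antimicrobial peptides, effectors of humoral immunity, were higher as a list (median 0.15, adjusted p = 0.0247; adjusted p = 0.715 with an estimated correlation). Of 19 tested members, 10 were higher and 1 lower on both arrays, with Mtk at 0.54 ± 0.0361, BomS1 at 0.60 ± 0.39, AttA at 0.39 ± 0.0721 and BomS3 at 0.41 ± 0.29. Its median was 0.45 on replicate 1, 0.15 on replicate 2 and 0.62 over both in the authors' values. The medians of the 2 lists lay at percentiles 4.25 and 96.3 of 10000 random lists matched on intensity. Both lists had 0 members past the threshold, over all genes or adjusted over the list alone. Both lost their call with plain background subtraction, with the sign of replicate 2 turned and in the authors' values. In the authors' values, where the median of all genes was 0.31, the cuticle median was 0.16 and the camera direction still downwards. With the sign turned, 6 cuticle genes were lower and 6 higher on both arrays (median -0.0295), and 2 antimicrobial peptides were lower and 6 higher (median 0.0510). The antimicrobial list also lost its call with median centring, and the cuticle list with the stricter filter on dim probes. Under that filter 2 antimicrobial members were left, too few to test, with medians of 1.23 on replicate 1 and -0.21 on replicate 2.

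**Figure D2:**
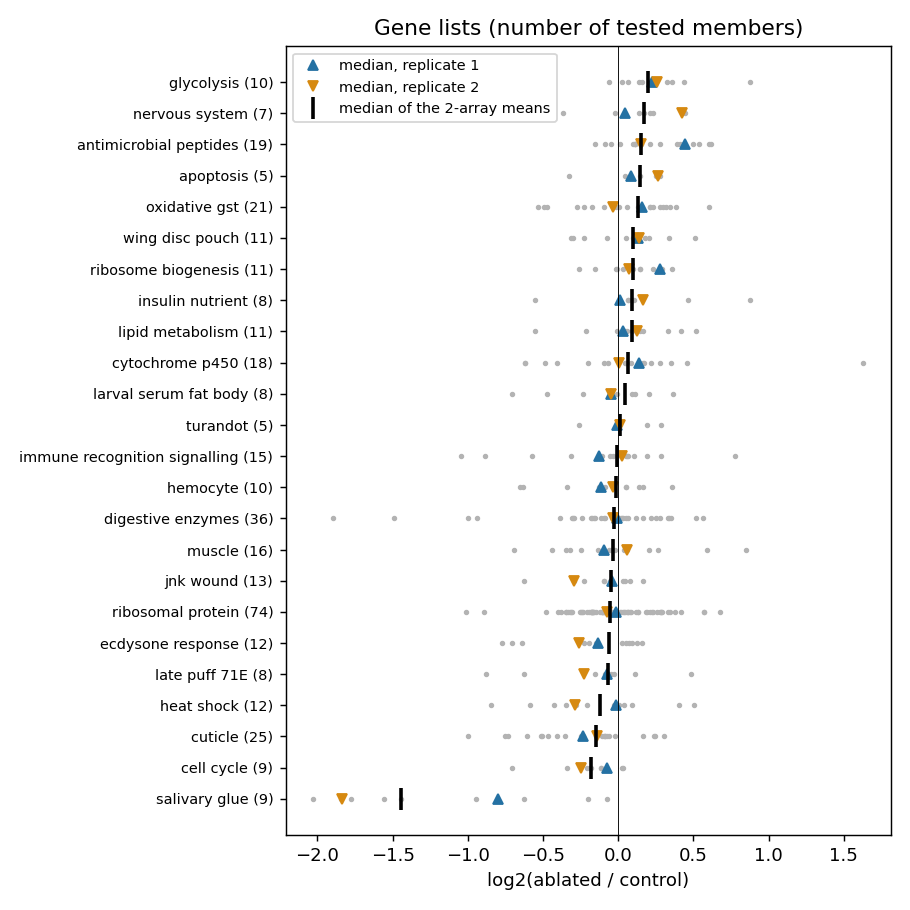
Log2 ratio of ablated to control larvae (x axis) for the 24 lists with at least 5 tested members (y axis, number tested in brackets). Grey points are genes (means of the 2 arrays), triangles are list medians on each array and black bars the medians of the means; the salivary glue list stands lowest at -1.44.

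The remaining lists did not pass, had 0 members past the threshold over all genes or adjusted over the list alone, and are given as values. Among lists of damage and stress signalling, the 13 tested genes of the JNK and wound list had a median of -0.0504 (adjusted p = 0.504), with Ets21C not well above background in the control larvae, with no bound, Gadd45 at -0.29 ± 0.11, puc at 0.16 ± 0.0805 and wg at -0.23 ± 0.69. Apoptosis genes (5 tested, median 0.14, adjusted p = 0.504) included grim at 0.28 ± 0.0194, Buffy at 0.25 ± 0.24, p53 at -0.33 ± 0.73 and Corp at 0.14 ± 0.50. The JAK/STAT list had 4 tested members and no test, with hop at -0.28 ± 0.37, Socs36E at 0.18 ± 0.61, upd3 not well above background in the control larvae, at -0.0430 on replicate 1 and 0.20 on replicate 2 and Ptp61F at 0.0320 ± 0.63. Turandot stress peptides (5 tested, median 0.0133, adjusted p = 0.774) included TotA at least 1.18-fold higher in the ablated larvae, TotE not well above background in the control larvae, with no bound, TotB at 0.19 ± 0.76 and TotZ not well above background in the control larvae, with no bound. Heat shock genes (12 tested, median -0.12, adjusted p = 0.409) included Hsp23 at -0.84 ± 0.33, Hsp83 at -0.59 ± 0.0958, Hsp70Ba at least 1.42-fold higher in the ablated larvae and Hsp70Ab not well above background in the control larvae, with no bound. In the oxidative stress list (21 tested, median 0.13, adjusted p = 0.504) stood GstD7 at 0.60 ± 0.00222, Prx6b at -0.53 ± 0.10, Duox at -0.47 ± 0.0374 and GstD2 at 0.38 ± 0.28. Cytochrome P450 genes (18 tested, median 0.0678, adjusted p = 0.631) included, beside Cyp6a23, Cyp310a1 at -0.62 ± 0.0417, Cyp9c1 at -0.62 ± 0.38 and Cyp4g1 at -0.41 ± 0.35. Of the genes without a bound, Ets21C read -0.86 on replicate 1 and -0.40 on replicate 2, and Hsp70Ab -0.34 and -0.52. TotE read -0.10 and -0.42, and TotZ -0.00560 and 0.0127. The ratios of Ets21C, Hsp70Ab and TotE thus ran lower in the ablated larvae.

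Immune recognition and signalling genes (15 tested, median -0.00872, adjusted p = 0.504) included spz at -1.04 ± 0.18, PGRP-LC at -0.88 ± 0.16, Tsf1 at 0.78 ± 0.53 and imd at -0.57 ± 0.28. Blood cell markers (10 tested, median -0.0164, adjusted p = 0.516) included PPO3 not well above background in the control larvae, with no bound, Col4a1 at -0.65 ± 0.51, Pxn at 0.36 ± 0.0433 and Sr-CI at -0.34 ± 0.0924. Among genes of the moulting hormone response (12 tested, median -0.0623, adjusted p = 0.220) were Hr3 with 2 probes that disagree (the brighter, not well above background in the ablated larvae, at -0.87 on replicate 1 and -0.68 on replicate 2; the other, above background in each group on 1 array, at -0.51 and 0.27), Fbp1 at -0.70 ± 0.0242, Eip74EF at -0.64 ± 0.16 and EcR not well above background in the control larvae, with no bound. Genes of ecdysteroid synthesis, 3 tested and without a test, gave shd at least 1.10-fold higher in the control larvae, ouib not well above background in the control larvae, with no bound and mld at 0.18 ± 0.40. The late puff genes at 71E (8 tested, median -0.0669, adjusted p = 0.409) gave Eig71Ef at least 1.78-fold higher in the control larvae, Eig71Ee at -0.63 ± 0.78, Eig71Ej at -0.15 ± 0.22 and Eig71Eg not well above background in the control larvae, at -0.62 on replicate 1 and 1.58 on replicate 2. Larval serum and fat body genes (8 tested, median 0.0420, adjusted p = 0.590, with a camera direction downwards against the sign of the median) gave, beside Fbp1, Lsp1alpha at -0.48 ± 0.27, Lsp2 at 0.36 ± 0.63 and Fbp2 at 0.20 ± 0.12. Of the genes without a bound, PPO3 read -0.46 on replicate 1 and -0.81 on replicate 2, and EcR -0.11 and -0.27, both lower in the ablated larvae. The ouib probe read 0.0452 and -0.61.

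Of the metabolic lists, glycolysis came nearest to the threshold (10 tested, median 0.20, adjusted p = 0.0677), with 6 members higher and 0 lower on both arrays, and included Pglym78 at 0.88 ± 0.88, Pgk at 0.44 ± 0.31, Ald1 at 0.32 ± 0.0825 and Eno at least 1.20-fold higher in the ablated larvae. With the sign of replicate 2 turned, 2 glycolysis members were higher and 2 lower on both arrays (median -0.0442). Insulin and nutrient genes (8 tested, median 0.0925, adjusted p = 0.474) included AkhR at least 1.83-fold higher in the ablated larvae, chico at -0.55 ± 0.26, Thor not well above background in the control larvae, at -0.00286 on replicate 1 and 0.94 on replicate 2 and tobi not well above background in the control larvae, at 0.19 on replicate 1 and -0.00293 on replicate 2. Lipid genes (11 tested, median 0.0907, adjusted p = 0.474) included SREBP at least 1.43-fold higher in the ablated larvae, Hnf4 at 0.33 ± 0.0197, bmm at 0.42 ± 0.54 and ACC at -0.55 ± 0.84. The mean log2 ratio of SREBP ran from 0.35 to 1.07 over processing alternatives, reaching below its bound. Digestive enzymes (36 tested, median -0.0308, adjusted p = 0.504) included, beside LysB and LysD, LysC at -0.94 ± 0.68 and Mal-A3 at 0.56 ± 0.34. For growth, the cell cycle list (9 tested, median -0.18, adjusted p = 0.153) gave Mcm7 at least 1.63-fold higher in the control larvae, pim at -0.34 ± 0.28, dup at -0.18 ± 0.0704 and aurB not well above background in the control larvae, with no bound. The mean log2 ratio of Mcm7 ran from -1.24 to -0.57 over processing alternatives, reaching nearer 0 than its bound. Ribosomal protein genes (74 tested, median -0.0523, adjusted p = 0.504) gave RpL34b at -1.01 ± 0.0925, RpS14b at -0.89 ± 0.32, RpS10a at 0.57 ± 0.0541 and RpL11 at 0.57 ± 0.37, and ribosome biogenesis genes (11 tested, median 0.0986, adjusted p = 0.504) gave Nnp-1 not well above background in the control larvae, with no bound, Surf6 at 0.29 ± 0.26, Nopp140 at least 1.10-fold higher in the ablated larvae and Nop56 at 0.23 ± 0.62. Of the genes without a bound, aurB read -0.0755 on replicate 1 and -0.30 on replicate 2, lower in the ablated larvae, and Nnp-1 0.60 and 0.12.

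Markers of tissues in the whole larva were also measured. Wing pouch genes (11 tested, median 0.0997, adjusted p = 0.504) gave, beside rn, dpp at least 1.42-fold higher in the ablated larvae, nub at 0.34 ± 0.28 and en not well above background in the control larvae, with no bound. The mean log2 ratio of dpp ran from 0.22 to 1.01 over processing alternatives, reaching below its bound. Further nub probes read -0.67 and 0.039. The en probe read 0.0919 on replicate 1 and 0.31 on replicate 2. Muscle genes (16 tested, median -0.0330, adjusted p = 0.685) gave Act57B at -0.44 ± 0.26, Mlc2 at 0.59 ± 0.61, Mf at least 1.27-fold higher in the ablated larvae and Prm at -0.69 ± 0.86. The mean log2 ratio of Mf ran from 0.14 to 6.25 over processing alternatives, reaching below its bound. Neural genes (7 tested, median 0.17, adjusted p = 0.409) gave cpx at 0.45 ± 0.0274, elav not well above background in the ablated larvae, with no bound, Frq1 at 0.17 ± 0.13 and Appl at -0.37 ± 0.97. The elav probe read -0.0305 on replicate 1 and 0.49 on replicate 2. Testis genes had 3 tested members and no test, with Mst84Dc at 0.40 ± 0.0896, bol at 0.33 ± 0.38 and aly at least 1.04-fold higher in the ablated larvae. Mst84Dc and bol were above background in both channels of both arrays, although the larvae are given as female. The source of this signal was not tested.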

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

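Control spots outside the gene probes carried signal above the level of empty spots. Of 188 DMNC spots, 20.7% on replicate 1 and 4.26% on replicate 2 were above background in either channel, as were 18.5% of 65 spike-in spots on replicate 1 and 3.08% on replicate 2, against 0 of 418 empty spots on each array, which allows a share of up to 0.718%. What DMNC stands for is not given in the sources used here, and no explanation was tested.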

How the results depend on the processing

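The settings with the mean of spot pixels, the turned sign and the separate channels without a dye term were chosen after the data were seen. The count of 0 called genes held under every alternative run except the turned sign, which gave 515. The count of genes at least 2-fold on both arrays (24) was 131 with background subtracted, 2 with the stricter filter, 191 in the authors' values, 346 with the sign turned and 150 at 1.5-fold, and 634 to 644 on single arrays. Camera called 3 lists. The number was 4 without background correction and with the mean over probes, 2 with median centring, and 1 with background subtracted and in the authors' values. It was 0 with the stricter filter, with the sign turned, with an estimated correlation and with fry. The correlation between arrays was -0.32 with background subtracted, -0.48 with no filter, -0.62 with the stricter filter, -0.36 in the authors' values and 0.53 with the sign turned. The egr and Tb probes were not above background in any channel, so their values measure no expression: for egr the mean was 0.0471 with background subtracted, 0.12 without correction, -0.0515 with median centring and 0.0272 with the mean of pixels; for Tb it was -1.57 with background subtracted and -2.08 in the authors' values; with the sign turned, rn was 0.64 and Ilp8 1.02, against 0.0315 as labelled. With the stricter filter on dim probes, 0 salivary glue genes were left to test. The list passed camera with the preset correlation under every other alternative except the turned sign. It did not pass with an estimated correlation or with fry. Glycolysis passed without background correction (adjusted p = 0.0226) and with the mean over probes (adjusted p = 0.0472). Leaving out 1 array leaves no residual degrees of freedom, so single arrays give values with no test, and no count of called genes or lists. The separate-channel model with a dye term could not be fitted, and the chromosome 3 test had 0 called genes. The test of ratios within arrays already pairs 1 ablated with 1 control RNA, so no further replicate block was fitted. Signal over background was low on replicate 2 (medians 1 and 10) and may limit all of these, which was not tested. Named genes whose mean moved by more than 1 on the log2 scale under an alternative with the labelled sign were, with their ranges, AkhR (0.84 to 2.14), Cyp310a1 (-0.75 to 0.43), Cyp6a23 (-0.82 to 2.05), Cyp9c1 (-0.68 to 1.24), Eig71Ee (-1.97 to -0.54), Eig71Ef (-2.48 to -0.76), Ets21C (-1.74 to -0.48), Gpdh1 (-6.17 to -0.97), Hsp23 (-4.76 to -0.58), Lcp65Ag1 (-4.94 to -0.52), LysB (-4.02 to -1.71), Mf (0.14 to 6.25), PPO3 (-5.09 to -0.47), Sgs3 (-5.47 to -1.38), shd (-2.54 to -0.15), stumps (-6.62 to -1.43). The cause of these changes was not tested. With median centring and in the authors' values the median of all genes moved too, to 0.14 and 0.31, so sign changes there can follow that shift. Under median centring every list given below except muscle lay under that median. In the authors' values ecdysone response, heat shock, jnk wound and muscle lay above it, and the other lists given lay under it. List medians and gene values that changed sign, all uncalled except for the salivary glue and cuticle lists, follow. With background subtracted these were digestive enzymes (0.00345), immune recognition signalling (0.0786), muscle (0.0257), Ptp61F (-0.0604), Appl (0.18), TotZ (-0.00222). With no background correction these were immune recognition signalling (0.0328), turandot (-0.11), Appl (0.15), TotZ (-0.12). With print-tip loess these were digestive enzymes (0.0326), larval serum fat body (-0.0348), muscle (0.00670), Corp (-0.0196), Ptp61F (-0.0753), Lsp2 (-0.00621). With median centring these were digestive enzymes (0.0709), ecdysone response (0.0733), heat shock (0.0693), hemocyte (0.0689), immune recognition signalling (0.11), jnk wound (0.12), late puff 71E (0.0442), muscle (0.16), ribosomal protein (0.0686), Eig71Ej (0.0325). With Aquantile after loess these were muscle (0.00809). With no filter on dim probes these were nervous system (-0.0437), turandot (-0.0274), wing disc pouch (-0.0428). With the stricter filter these were ecdysone response (0.0515), muscle (0.0548). In the authors' values these were cell cycle (0.0220), cuticle (0.16), digestive enzymes (0.22), ecdysone response (0.38), heat shock (0.39), hemocyte (0.0945), immune recognition signalling (0.27), jnk wound (0.37), late puff 71E (0.10), muscle (0.33), ribosomal protein (0.29), p53 (0.11), pim (0.28), aurB (0.0220), Cyp6a23 (-0.82), Cyp310a1 (0.43), Cyp9c1 (1.24), EcR (0.51), Hsp70Ab (0.51), imd (0.15), hop (0.12), Lsp2 (-0.33), Eig71Ej (0.10), Appl (0.0135), en (-0.13). With the mean over probes these were immune recognition signalling (0.0433), nub (-0.0967). With the mean of spot pixels these were digestive enzymes (0.00976), immune recognition signalling (0.0134), aurB (0.0153), upd3 (-0.0316), Ptp61F (-0.0371), Gadd45 (0.0241). With the sign of replicate 2 turned these were apoptosis (-0.17), cell cycle (0.0498), digestive enzymes (0.0111), ecdysone response (0.0347), glycolysis (-0.0442), heat shock (0.11), hemocyte (0.0480), insulin nutrient (-0.17), larval serum fat body (-0.0414), late puff 71E (0.0576), lipid metabolism (-0.0876), ribosomal protein (0.0275), salivary glue (0.34). Single genes were not listed with the sign turned, where 54 of 110 named genes changed sign.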

Other observations

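Tests of weak signal, of dye bias in the glue genes, of related glue probes, of the stage of the larvae and of chromosome 3 were chosen only after the results were seen, as were the comparison restricted to brighter probe pairs and that between arrays for the probes of these pairs.

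Beyond the genes named above, 11 further genes were at least 2-fold lower on both arrays, with means from -1.47 to -1.05. They include polybromo, a chromatin remodelling subunit, and ND-B14, a subunit of respiratory complex I, named here after their values were seen. None passed the adjusted test, and 1 of them, Andorra, was above background in all channels of both arrays.

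The first pattern is that log2 ratios followed the wavelength more than the genotype. If the dye record of 1 array had been exchanged, the part shared by wavelength would be an RNA difference, and different probes of 1 gene should share it. Over 310 pairs its Spearman rho was -0.12 (95% bootstrap interval -0.24 to -0.00757), below the bound of 0.5 set in advance, while intensities of the same pairs agreed at 0.47 (0.36 to 0.57). That bound was high, since intensities themselves reach it only within their interval, but the wavelength part also lay below their whole interval. In 68 brighter pairs rho was -0.11 (-0.37 to 0.15), and the part shared by genotype gave 0.0778 over all pairs. In the 620 probes of all these pairs the wavelength part was repeated from array to array (rho = 0.28, 0.19 to 0.36) and had an SD of 0.68, against 0.34 for the part shared by genotype, so it was not noise alone, and yet it was not shared by probes of 1 gene. The part shared by genotype, the RNA difference if the record is right, was not clearly shared by probes either (interval -0.0324 to 0.188). The outcome set in advance against an exchanged record was met, but the test does not separate the 2 readings. An exchanged record as the source of the pattern across genes therefore stays open, and single genes are not settled. Spots below background are argued against as the source by r = -0.61 (95% bootstrap interval -0.66 to -0.55) among genes above background in all channels. Among the other tested genes r was -0.50. Random error of dim spots would only pull r towards 0, so the test says nothing about systematic effects of low signal. Plain background subtraction moved r to -0.32. A dye bias of single probes may remain, but its test was undecided: the SD between probes over that between copies was 2.01 on replicate 1 and 1.09 on replicate 2.

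The second pattern is the lower salivary glue genes. A dye effect keeps its sign between wavelengths whatever the dye record, and so would put the members on opposite sides on the 2 arrays, yet 77.8% were lower on both (7 of 9, exact 95% interval 39.99 to 97.19% if genes were independent), and the median of -1.44 was lower than all of 10000 intensity-matched random lists. The share restates the pattern, in the list with the smallest p of 24, so it is no separate test of a dye effect. Random lists take genes as independent, while the estimated correlation in this list was 0.56. With the sign of replicate 2 turned, 1 member was lower and 1 higher on both arrays. In the authors' uncentred values 3 of 7 were below 0 on both, where the median of all values on replicate 1 was 0.487. A dye effect as part of the source stays open. Signal shared within 2 families was argued against as the whole source. With Sgs3 kept for Sgs3, Sgs7 and Sgs8, and Sgs5 for Sgs5 and Sgs5bis, the median was -0.79. This was lower than all of 10000 intensity-matched random lists. The ng genes of the list were not reduced in this way, and the random lists take genes as independent. Signal shared across the remaining members therefore stays open. A younger stage of the ablated larvae may account for the pattern, as a hypothesis. The moulting hormone list did not pass camera (adjusted p = 0.220), though its direction was downwards. Of its 12 tested members 5 were lower and 1 was higher on both arrays, and 6 differed in sign between arrays, which leaves this open. The labels give both groups the same larval stage, and the genotype difference itself stays open too. Sgs3, Sgs5, Sgs7 and Sgs8 all lie on chromosome 3, which differs between the groups.

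The third pattern is that more genes were at least 2-fold lower than higher. The groups differ in chromosome 3, by genotype; 12 of 22 such lower genes with a known chromosome lay on chromosome 3 (54.5%) against 45.1% of other tested genes (Fisher's exact test, two-sided, p = 0.398; odds ratio 1.46, 95% interval 0.577 to 3.78), too few to decide. Without the glue genes it was 8 of 18 (44.4%, odds ratio 0.973, Fisher's exact test, p = 1). Of the settings named in advance, print-tip loess left the share of lower genes at 95.7%, against 95.8% as reported, and no background correction gave 76.9%, between the bounds set. Normalization may account for part of the pattern, and the share was 63.2% with median centring. It was 16.2% in the authors' values, where most such genes were higher, and 50.6% with the sign of replicate 2 turned, so the pattern rests on the processing and on the labelled direction.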
